A study of Caenorhabditis elegans with 4 samples.

How the data were processed

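The series profiled HTZ-1 by ChIP-seq in N2 embryos of mixed stages and both sexes, grown at 20 °C per the series' design text. Per the labels' protocols, embryos were fixed with 2% formaldehyde for 30 min, chromatin was sonicated, 10% of the extract was kept as input, and single-end barcoded libraries were made. The 4 samples were grouped from their titles into HTZ-1 ChIP (replicates 1 and 2) and input (replicates 1 and 2). The input samples are not analysed here.

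The data are 3 peak lists in GFF3 format, all on WormBase WS220 per the file headers. The submitters' processing notes name the aligner BWA, without a version, and the build ce10. Per the files' source column, the replicate lists come from MACS and the combined list from MACS v2. The sources used here do not give the thresholds, the filters on reads, the role of the input or how the combined list was made. Each deposited peak carries a score from the authors' caller. Its scale is not given in the sources used here. In the replicate lists the scores run from 50.1 to 3228 and from 50.2 to 3233, with many peaks tied at 3100, and in the combined list from 1.35 to 223. Scores were therefore compared between the replicates only as ranks over overlapping pairs, and otherwise within a list, as ranks, as shares of peaks in the upper 50% or as medians that describe a class of peaks, and no ratio of scores is given. Deposited start and end positions are the other values used. Peak numbering ran without a gap in each list and no peaks overlapped within a list. The combined list carries no sample name and is taken here to draw on both replicates, so it has no replicate error of its own. The read depth is unknown, and no interval for read counts can be given.

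Peaks of 2 lists were counted as overlapping when they shared at least 1 bp. Overlap was set against 1000 circular shifts of one list along each chromosome (one-sided permutation test). Chromosome spans were taken as the furthest peak end in any list, since no chromosome lengths of this build were used here. They sum to 100.1 Mb. Densities were counted from peak midpoints in bins of 1 Mb, a last bin being scaled by its length if over 0.5 Mb and otherwise left out, which gave 100 bins. X was compared with chromosomes I to V, and the central 1/3 of each autosome by length with the rest (the arms), by two-sided permutation of bin labels (100000 resamples). Intervals of ratios are 95% delta-method intervals over bins, chosen after a percentile bootstrap had been tried on simulated lists, and those of shares of peaks are exact binomial intervals. Bins of one chromosome are not independent, so bin p values can be too small. Exact tests with the chromosome as the unit were run for the main contrasts and for those of score, width and weak peaks, and cannot go below 0.167 for X or 0.0625 for arms. The X to autosome ratio of covered length is given with the mean covered length. Adjusted p values are Benjamini-Hochberg values over the relations stated.

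The sample groups, the main tests and the rule for named peaks were set before the data were examined. With no annotation of the build, that rule takes the 10 highest-scoring combined-list peaks that overlap both replicates, and the highest-scoring such peak on each chromosome. Planned comparisons of peaks with gene 5' ends, gene parts and fixed gene lists required an annotation of WS220. The gene table at hand is on the assembly WBcel235, so they were not run, positions were not converted between builds and no genes are named. The alternatives tried were the top 50% of peaks by score, stricter overlap, each replicate list alone, peaks present in both replicates, other bin sizes, covered length and other limits of the arms. Several were added after the data were examined: the lower 50% by score, merging of peaks less than 1 kb apart, subsets of autosomes, the chromosome as the unit, pairs with both scores below 3100, shares by score rank in place of median scores, and redraws of peak positions that keep widths and spacing.

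Closeness of peaks and long distances between them were set against 1000 redraws within 1 Mb bins, in which each peak kept its width and peaks did not overlap, or lay at least 1 kb apart for merged peaks. Closeness was first set against redraws of midpoints alone, which ignore widths and spacing, and both results are given. The tests were run on simulated lists. For replicate-sized lists of 3848 peaks, the shift test called 2 of 40 independent pairs and 40 of 40 pairs that shared 10% of their peaks. For 5000 peaks, the redraw test called 2 of 40 lists placed at random and 40 of 40 with 10% of peaks placed beside another. For 7546 peaks, the bin test called X in 5 of 100 simulations of equal density. With X thinned to 0.5 of the density it called X in 100 of 100, and 90 of those 100 intervals held the true ratio. The intervals of ratios were thus somewhat narrower there than their nominal 95%. In these simulations peaks were placed independently, with equal density on all autosomes. Density differs between autosomes in the deposited lists, so these rates do not carry over to them, and the intervals there can be narrower still. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.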

Results

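HTZ-1 is the C. elegans form of the histone variant H2A.Z, which replaces H2A in a subset of nucleosomes and in many organisms lies next to transcription start sites. Its genomic distribution was profiled by chromatin immunoprecipitation and sequencing (ChIP-seq) in wild-type N2 embryos of mixed stages, with a rabbit polyclonal antibody raised against the N-terminus of the protein. The series holds 4 samples, 2 HTZ-1 ChIP samples and 2 input DNA samples with the same replicate numbers. Each ChIP replicate came with a list of called peaks, and a further list covered the series as a whole and is called the combined list here. The input samples were not analysed here, because no file of theirs was used. The comparisons that the design allows are therefore how well the 2 ChIP replicates place the variant at the same sites, how the combined list relates to them, and how the sites are spread over the genome. The number of sequenced reads behind each list is unknown, so the precision of a single peak score cannot be given.

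HTZ-1 was called at discrete sites spread over all 6 chromosomes. Replicate 1 had 3848 peaks covering 10.6 Mb and replicate 2 had 3650 peaks covering 9.42 Mb, or 10.6% and 9.41% of the span between chromosome starts and the furthest peak. The peaks of both replicates were of similar width, with a median of 2425 bp in replicate 1 (quartiles 1981 and 3046.5 bp) and 2388.5 bp in replicate 2 (quartiles 2007 and 2796 bp). The combined list held 7546 narrower peaks, with a median width of 720.5 bp (quartiles 313.25 and 1335 bp), and covered 6.65 Mb, or 6.64% of the span. The replicate lists and the combined list carry different caller names in their files, and their scores are on different scales, so the replicates' scores were compared with each other only as ranks, and those of the combined list only within it.

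The 2 ChIP replicates placed HTZ-1 largely at the same sites. Of the replicate 1 peaks, 3306 overlapped a replicate 2 peak by at least 1 bp, which is 85.9% (exact 95% interval 84.78% to 87%). Of the replicate 2 peaks, 3417 overlapped a replicate 1 peak, which is 93.6% (92.8% to 94.4%). These intervals cover counting error only, and neighbouring peaks are not independent. When one list was shifted around each chromosome 1000 times, the mean overlap was 20.4% for replicate 1 and 21.6% for replicate 2, and the highest was 28.04% and 29.84%. In both directions the one-sided permutation p was 0.001, the smallest that 1000 shifts can give, and it describes placement in these 2 lists. The labels do not say whether the replicates came from separate cultures, so the p-values concern these samples only, and the spread between them may be technical.

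The sites found in only 1 replicate were mostly weakly scored. The 542 replicate 1 peaks without a partner had a median score of 95.3, against 1136 for those with one, and 92.4% of them lay in the lowest 25% of the list by score. The 233 unpartnered replicate 2 peaks had a median score of 95.5, against 679 for the partnered ones, and 81.5% lay in the lowest 25%. Weak peaks were also found among the partnered ones, of which 13.9% in replicate 1 and 21.2% in replicate 2 lay in the lowest 25%. Over the 3306 overlapping pairs the scores of the replicates ranked alike, with a Spearman rho of 0.906 across peaks (95% bootstrap interval 0.899 to 0.912). Peaks are not independent replicates, so no p is given for this rank correlation. Many high scores are tied at 3100. In all, 517 peaks of replicate 1 and 177 of replicate 2 stood at that value or above it, and rho was 0.873 over the 2771 pairs below that value.

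The number of sites per 1 Mb bin also matched between replicates. Across all 100 bins the Spearman rho was 0.979 (permutation p = 1e-05, adjusted p = 2e-05 over 14 relations, the raw p being the smallest that 100000 resamples can give) and Pearson's r was 0.979 (permutation p = 1e-05). Without the 2 bins farthest from the median, r was 0.978. Within single chromosomes rho ranged from 0.910 on V to 0.961 on III (adjusted permutation p between 2e-05 and 5.3e-05).

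The combined list was made up largely of sites present in both replicates, most of them strongly scored, and a large weak fraction that the replicate lists did not contain. Of its 7546 peaks, 4344 (57.6%, exact 95% interval 56.4% to 58.7%) overlapped peaks of both replicates, with a median score of 55.3 and a median width of 1235 bp. That share depends on the overlap required. It was 56.9% when at least 50% of the shorter peak had to overlap and 24.04% when at least 50% of both peaks had to. Many combined-list peaks are too narrow to cover 50% of a replicate peak, so the lower share need not mean fewer shared sites. A further 1046 (13.9%) met replicate 1 only, with a median score of 8.40, and 395 (5.23%) met replicate 2 only, with a median score of 7.94. The remaining 1761 (23.3%, interval 22.4% to 24.3%) met neither. These had a median score of 5.44 and a median width of 268 bp, and 1 of them scored above the median of the peaks found in both. In the other direction almost every replicate peak was represented, 3846 of 3848 in replicate 1 and 3618 of 3650 in replicate 2. One replicate peak often corresponded to several combined-list peaks, since 27.2% of the replicate 1 peaks and 23.3% of the replicate 2 peaks held at least 2.

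**Figure D1:**
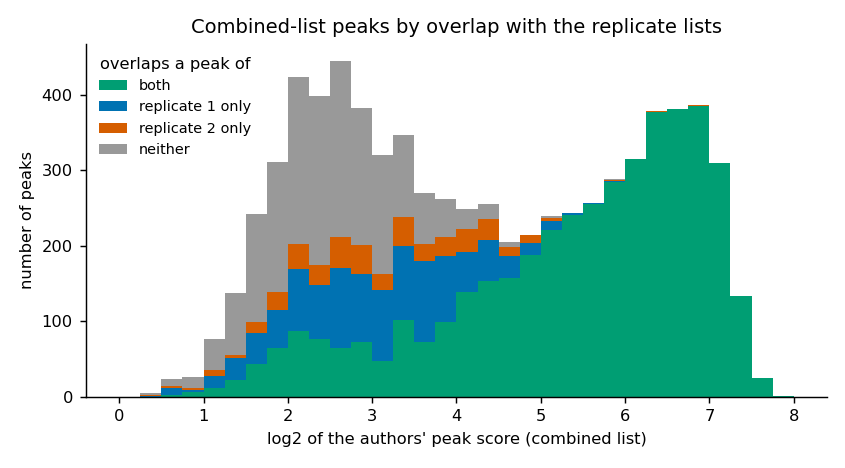
Number of combined-list peaks (y axis) by the log2 of their score as the authors' caller gave it (x axis), stacked by whether they overlap a peak of both replicates, of 1 replicate or of neither. Most of the 4344 peaks found in both replicates lie in the right-hand mode, with some at low scores. The 1761 found in neither lie mostly on the left, with a median score of 5.44.

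The strongest sites found in both replicates were spread over the autosomes. They also scored high in each replicate list. This may be partly built in, since the combined list is taken to draw on both replicates. All coordinates are 1-based positions on WormBase WS220, and which genes lie at them was not analysed here, because the gene table at hand is on another assembly. The highest-scoring combined-list peak found in both replicates was at chromosome I, 1609501 to 1611051, with a score of 223.15. It was followed by peaks at chromosome IV, 1054122 to 1057548 (score 208), and at chromosome II, 13722749 to 13726601 (score 204). The next were at chromosome I, 662855 to 664417, and chromosome II, 2786334 to 2788017 (both 199), and at chromosome III, 10459648 to 10462013 (199). The list of 10 was completed by chromosome IV, 9403125 to 9404370 (196), chromosome V, 17869983 to 17872017 (195), chromosome I, 322577 to 324634 (192), and chromosome II, 14153499 to 14155258 (192). Of these 10 sites, 9 stood at the tied score of 3100 in each replicate. That score or a higher one was held by 13.4% of all replicate 1 peaks and 4.85% of all replicate 2 peaks. The exception, on chromosome IV at 9403125, had scores of 2378 in replicate 1 and 2457 in replicate 2. The first peak on X came at rank 115, at 238859 to 240252 with a score of 159, and it stood at 3100 in both replicates.

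HTZ-1 sites were unevenly spread over the chromosomes and were sparsest on X, the chromosome that is subject to dosage compensation in hermaphrodites. In the combined list, chromosomes I and III had the highest densities, with 113 ± 19.7 (SD, n = 15 bins) and 108 ± 21.1 (SD, n = 14 bins) peaks per Mb. Chromosomes IV and II were intermediate, with 77.4 ± 21.3 (SD, n = 17) and 75.1 ± 15.3 (SD, n = 15). Chromosome V, which carries large families of chemoreceptor genes, had 52.7 ± 9.19 (SD, n = 21), and X had 42.3 ± 10.6 (SD, n = 18). The 740 peaks on X made up 9.81% of the list. Peaks covered 10.2% of the span of chromosome I and 10.0% of III, against 4.47% of V and 3.19% of X. Both replicate lists gave X the lowest density, 23.7 ± 5.28 and 20.9 ± 6.18 peaks per Mb (SD, n = 18 bins), and V the next lowest, 26.9 ± 8.17 and 25.7 ± 7.99 (SD, n = 21 bins).

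**Figure D2:**
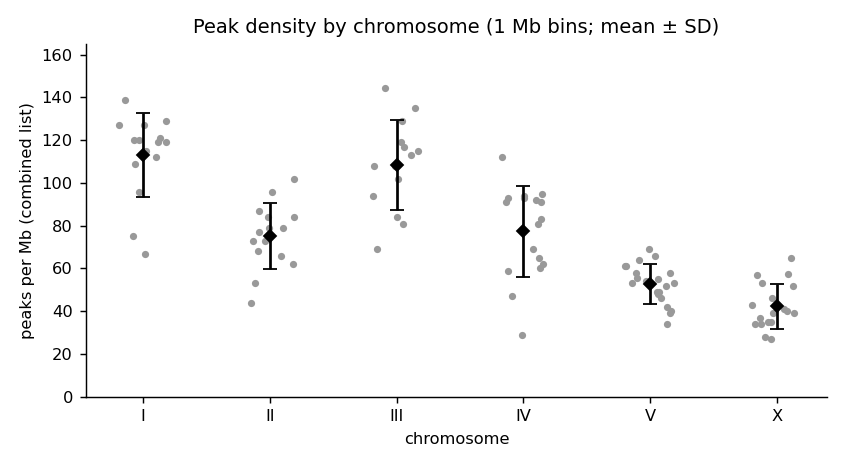
Combined-list peaks per Mb (y axis) in 1 Mb bins of each chromosome (x axis); grey points are bins, black diamonds their mean and bars 1 SD. The bins of X centre on 42.3 peaks per Mb and those of chromosome I on 113.

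X carried 0.513 times as many combined-list peaks per Mb as the 5 autosomes together (95% interval 0.442 to 0.596, 18 against 82 bins, two-sided permutation p = 1e-05, the smallest that 100000 resamples can give). The ratio was 0.569 (0.495 to 0.654, permutation p = 2e-05) in replicate 1 and 0.526 (0.444 to 0.622, permutation p = 1e-05) in replicate 2. Measured as covered length, X held 31.96 ± 9.10 kb of peak per Mb against 73.6 ± 27.6 kb on autosomes, a ratio of 0.434 (0.368 to 0.513, permutation p = 1e-05). Against chromosome V alone, a comparison added after the data were examined, the combined-list ratio was 0.804 (0.693 to 0.932, permutation p = 0.003). That comparison was not run on the replicate lists. With the chromosome rather than the bin as the unit, X was the lowest of 6, and the exact permutation p of 0.167 is the smallest that this design allows.

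Sites on X ranked lower by score than those on autosomes within each replicate, and were narrower. The share of replicate 1 peaks in the upper 50% of the list by score averaged 25.24% ± 10.6 per bin on X and 51.5% ± 9.68 on autosomes (difference -26.3 percentage points, 95% interval -32.03 to -20.6, permutation p = 1e-05). In replicate 2 it was 24.9% ± 10.9 against 51.7% ± 9.22 (difference -26.8, interval -32.6 to -21.005, permutation p = 1e-05). The combined list showed no detectable difference over all its peaks, with 48.9% ± 9.34 against 50.2% ± 9.22 (interval of the difference -6.36 to 3.88, permutation p = 0.61). Among its peaks present in both replicates, the share in the upper 50% of that set was 34.1% ± 13.1 on X and 51.7% ± 9.94 on autosomes (difference -17.6, interval -24.5 to -10.7, permutation p = 1e-05). Averaged over bins, the median width per bin was 2079 bp on X against 2446 bp on autosomes in replicate 1 and 2140 against 2398 bp in replicate 2 (permutation p = 1e-05 in each). In the combined list these bin averages were 686 against 740 bp, which did not differ detectably (ratio 0.927, interval 0.798 to 1.08, permutation p = 0.31). With the chromosome as the unit, X was lowest in each of the replicate contrasts, at the smallest exact permutation p of 0.167.

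Autosome arms and centres differ in their make-up, since the arms of C. elegans autosomes are richer in repeats and the centres in conserved, broadly expressed genes. Counted as combined-list peaks, the arms (the parts of each autosome outside its central segment, which was set as 1/3 of its length) and the centres did not differ detectably. The means were 81.8 ± 30.8 (SD, n = 55 bins) and 83.8 ± 24.3 (SD, n = 27 bins) peaks per Mb, a ratio of 0.976 (95% interval 0.836 to 1.14, two-sided permutation p = 0.77). The replicate lists gave lower densities on the arms. Replicate 1 had 38.5 ± 15.0 peaks per Mb on arms and 48.1 ± 13.4 in centres (ratio 0.801, 0.686 to 0.934, permutation p = 0.0065). Replicate 2 had 36.3 ± 13.9 and 46.8 ± 12.5 (ratio 0.776, 0.669 to 0.901, permutation p = 0.0015). The combined list gave the same direction when only its top 50% of peaks by score were counted (ratio 0.793, 0.676 to 0.930, permutation p = 0.0063). In each of these 3 sets all 5 autosomes had the lower density on their arms, and the exact sign-flip permutation p of 0.0625 is the smallest that 5 chromosomes allow.

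The opposite was seen for weak sites. In the lower 50% of the combined list by score, a set chosen after the data were examined, the arms had 43.7 ± 17.4 peaks per Mb and the centres 35.8 ± 13.3 (ratio 1.22, 1.02 to 1.47, permutation p = 0.04). The share of peaks in the upper 50% by score averaged 46.5% per arm bin and 57.6% per centre bin, a difference of -11.1 percentage points (interval -14.7 to -7.52, permutation p = 1e-05). This share and both densities by score come from 1 division of the list and are not separate findings. Averages over bins of the median width per bin were 642.5 bp on arms and 937 bp in centres in the combined list (permutation p = 1e-05) and 2386 and 2566 bp in replicate 1 (permutation p = 4e-05). In replicate 2 these averages were 2390 and 2416 bp, which did not differ detectably (permutation p = 0.47). The lower 50% was denser on the arms of all 5 autosomes, at the smallest exact sign-flip permutation p of 0.0625. On X the arms had 44.8 ± 11.6 (SD, n = 12 bins) and the centre 37.5 ± 6.89 (SD, n = 6 bins) combined-list peaks per Mb, a ratio of 1.19 (interval 0.910 to 1.57, two-sided permutation p = 0.18).

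**Figure D3:**
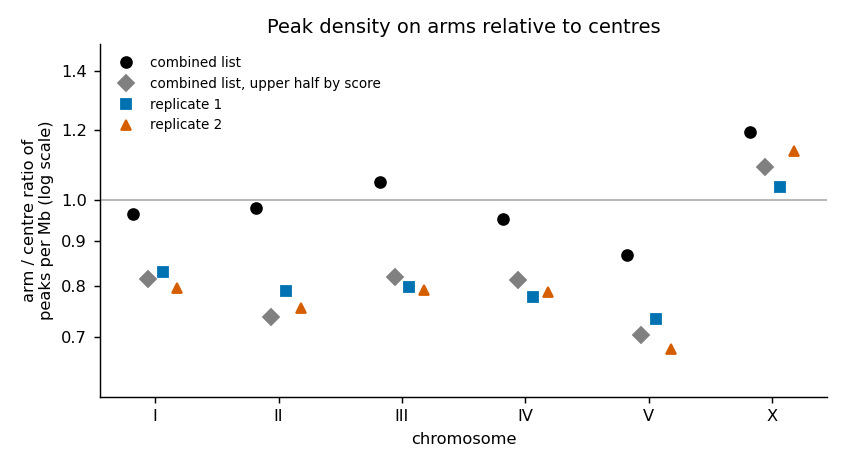
Ratio of mean peak density on the arms to that in the centre (y axis, log scale) for each chromosome (x axis), in the combined list, its upper 50% by score and each replicate list; the line marks equal density. In the replicate lists and the upper 50% the ratios of chromosomes I to V all lie below 1 and those of X above 1.

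**Figure D4:**
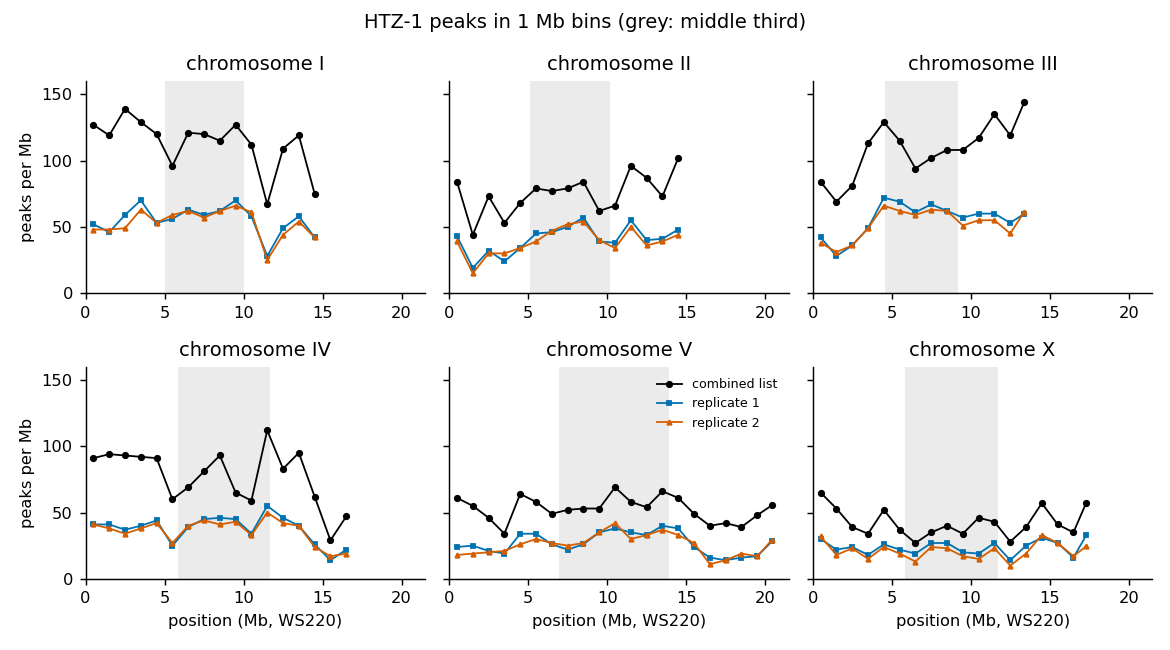
Peaks per Mb (y axis) in 1 Mb bins along each chromosome (x axis, position in Mb on WS220) for the combined list and both replicates; the grey band is the centre as defined for the arm comparison. The replicate curves run together, with a Spearman rho of 0.979 over the 100 bins, and the lowest bins of the combined list are on X, at 27 and 28 peaks per Mb.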

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

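The test of the difference between X and autosomes was chosen after the densities of arms and centres had been seen. In a test over bins, the contrast between arms and centres differed on X from that on the autosomes. After dividing each bin by its chromosome's mean, covered length on arms was 1.10 times that of the centre on X and 0.817 times on the autosomes, a log2 difference of 0.42 (permutation of the X and autosome labels within arms and within centres, p = 0.012, adjusted p = 0.019, 10000 resamples). The ratio on X alone did not differ detectably from 1 (interval 0.781 to 1.54, permutation p = 0.55, and 0.82 and 0.56 in the replicates). The same test gave log2 differences of 0.44 (permutation p = 0.018) in replicate 1 and 0.53 (permutation p = 0.0036) in replicate 2. Over the 8 combinations of list and measure tested, the adjusted permutation p values ran from 0.0072 to 0.03. These combinations draw on the same libraries and are not separate findings. X supplies 12 arm and 6 centre bins of a single chromosome, so the difference rests on that chromosome. By chromosome, the covered-length ratio in the combined list was 1.10 on X and from 0.737 on V to 0.878 on III among autosomes. An exact permutation test with the chromosome as the unit was not run for this contrast and could not go below 0.167.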

How the results depend on the processing

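The lower 50% by score, the merged peaks, the subsets of autosomes, the chromosome as the unit, the shares by score rank, the redraws with spacing and the pairs below 3100 were chosen after the data were examined. Overlap between replicates stayed above the shifted lists in the 3 alternatives, at 82.4% to 86.9% for replicate 1 and 86.9% to 93.5% for replicate 2. The share of combined-list peaks found in both replicates was 56.9% with an overlap of at least 50% of the shorter peak. It was 24.04% with a reciprocal overlap of at least 50%. Median widths were 720.5 bp in the combined list and 2425 and 2388.5 bp in the replicates. Many combined-list peaks therefore cannot cover 50% of a replicate peak. In the top 50% of each list by score the share was 50.8%. Both replicate lists were cut to their top 50% there as well, so partners in their lower 50% no longer counted. The share can fall for that reason alone, so it does not show that strong peaks were shared less often. The score rank correlation was 0.740 in the top 50%, 0.915 with reciprocal overlap and 0.873 over pairs below 3100. The X to autosome ratio lay between 0.434 and 0.804 in the 10 alternatives run on bins, with permutation p of 0.003 or lower. With the chromosome as the unit it was 0.496, and the exact permutation p of 0.167 is the smallest that 6 chromosomes allow. The arms against centres contrast passed the threshold at ratios of 0.793 in the top 50% by score, 0.817 for peaks in both replicates, 0.843 by covered length (permutation p = 0.046) and 0.776 to 0.801 with the list of 1 replicate alone, which also changes the caller. It reversed to 1.22 in the lower 50% by score (permutation p = 0.04); the cause was not tested. In 5 further alternatives it did not pass. These include the chromosome as the unit (ratio 0.960, exact sign-flip permutation p = 0.3125), which could not pass, since its smallest p is 0.0625. No paired analysis was possible because no file of the input samples was used here. Results at gene 5' ends, by gene part and for gene lists, with their alternatives, and peaks per protein-coding gene 5' end were not run, since no WS220 annotation was used here. Read depth is unknown, which limits what can be said of weak peaks.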

Other observations

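The 10 longest spans without any HTZ-1 peak in the 3 lists lay on chromosomes IV, V and X. The longest were chromosome IV, 15985341 to 16239358 (254 kb), and chromosome V, 3777089 to 4028717 (252 kb). Of 69 peak-free spans of 100 kb or more, 26 were on X, 23 on V and 10 on IV, 7 on II, 2 on I and 1 on III. After peaks less than 1 kb apart were merged, 72 distances between neighbouring midpoints reached 100 kb, against 23 to 49 in 1000 redraws within 1 Mb bins that kept widths and spacing (permutation p = 0.001, the smallest they can give). On V the count was 24 against 2 to 20 (permutation p = 0.001), and on X it was 26 against 8 to 27 (permutation p = 0.005). In the replicate lists the counts on X were 44 and 44, with permutation p of 0.03 and 0.5.

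The widest combined-list peak lay near the right end of chromosome I, 15060258 to 15071342 (11085 bp, score 23.97), and overlapped no peak of either replicate. The fourth widest, on X at 109602 to 114270 (4669 bp, score 20.0), met replicate 2 only. Combined-list peaks also began at position 1 of chromosomes I and X, with scores of 19.0 and 5.63. On chromosome I the first replicate peaks started at 3179 and 15779, and on X at 33307 in replicate 1 and at 6 in replicate 2, where a peak with a score of 89.5 overlapped the combined-list peak.

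The tests of weak peaks (the share and ratios by score) and of pieces on autosome arms were added after the arm densities of all 3 lists had been seen, and that of closeness in the combined list after the distances between neighbours had been summarised, each before its own result was seen. The redraws that keep widths and spacing, the test of merged peaks, the counts of long distances, the comparison of X with II, IV and V, the share by score on X and the tests of peaks in neither replicate were chosen after. The X ratio in each replicate list was planned, and its use against a cause particular to the combined list came after. The lower density on X was not particular to the combined list, since the higher of the replicate lists' upper interval bounds for the ratio was 0.654. All 3 lists come from MACS or MACS v2, so a cause that they share stays open. The bins also argue against the dense chromosomes I and III as the only source, as the combined-list upper bound against II, IV and V was 0.735. That interval is over bins, so it does not cover ordinary variation between chromosomes. Weaker scores on X that fall under the threshold may contribute, as fewer replicate peaks on X lay in the upper 50% by score (-26.3 and -26.8 percentage points), a rank that may also follow peak width. The share of combined-list peaks in the upper 50% by score differed by -1.24 percentage points (permutation p = 0.61), which leaves this open. The number and expression of genes on X, a biological candidate, was not tested.

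Combined-list peak counts did not differ detectably between autosome arms and centres (ratio 0.976, interval 0.836 to 1.14), while both replicate lists were sparser on arms (0.801 and 0.776). A candidate explanation is that weak peaks, commoner on arms, enter the combined list only. The share of its peaks in the upper 50% by score was lower on arms by -11.1 percentage points (permutation p = 1e-05). That restates the ratios of 0.793 and 1.22 of the upper and lower 50%. The share was also lower on arms in replicates 1 and 2 (-10.8 and -5.30 percentage points, permutation p = 1e-05 and 0.014). Lower scores on arms were therefore not particular to the combined list. Each replicate 1 peak also held 1.08 times as many combined-list peaks on arms as in centres (permutation p = 0.0059), and merging peaks less than 1 kb apart gave a ratio of 0.926 (permutation p = 0.31). Whether repeats or mappability bear on the weak peaks was not tested, and no biological explanation was.

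A prediction of weak signal under the replicate lists' threshold held for the 1761 combined-list peaks in neither replicate. Of the 1761, 72.4% scored below the 10th percentile of the peaks found in both. The peaks in 1 replicate only, another set, had partners in the lowest 25% of that replicate's list in 67.8% and 61.0% of cases. Peaks missing from both replicate lists would tend to score low whether they are weak signal or background. The scores therefore cannot tell weak signal from background. An even scatter over the genome is argued against by a Spearman rho of 0.527 across the 100 bins with the peaks found in both (permutation p = 1e-05), a relation that was not detected within chromosomes (rho -0.354 to 0.423, adjusted permutation p 0.14 to 0.89). An even scatter within chromosomes is argued against by their arm to centre ratio of 1.39 on autosomes (permutation p = 0.0014). Background that differs between chromosomes and regions stays open without the input.

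A hypothesis that HTZ-1 peaks lie closer together than their density per Mb gives held for the combined list, where 71.1% of peaks had a neighbouring midpoint within 5 kb, against 54.1% to 58.1% in redraws of midpoints alone, set before this share was seen, and 50.1% to 54.1% in redraws that kept widths, chosen after (permutation p = 0.001 in each, the smallest 1000 draws can give). In replicates 1 and 2 the direction turned with the redraw, as the shares of 30.6% and 29.5% lay below redraws of midpoints alone (31.9% to 37.1% and 30.4% to 36.4%, one-sided permutation p = 1 in each) and above those that kept widths (17.1% to 22.6% and 17.6% to 23.01%, permutation p = 0.001 in each). After merging peaks less than 1 kb apart the share was 46.6%, within redraws of midpoints alone (43% to 47.98%, permutation p = 0.18), which allow distances that merged peaks cannot have, and above those that kept widths and this spacing (30.5% to 34.97%, permutation p = 0.001). Only the latter, chosen after, argues against pieces less than 1 kb apart as the whole cause. Pieces of one region that lie further apart stay separate after merging, so the test does not bear on them. An uneven spread of genes within 1 Mb may give the same result and was not tested.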
